A study of Arabidopsis thaliana with 6 samples.

How the data were processed

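The series compared whole plants of wild-type Arabidopsis thaliana (accession Col-0) with the mutant sni1 in the same background, with 3 arrays per genotype and 6 in all. Per the labels, seeds were kept for 3 days at 4 °C, plants grew on soil in a growth room at 22 °C, and the samples were at growth stage 3.90. Total RNA was labelled with biotin and hybridised to the Affymetrix ATH1 array, which measures each transcript with a set of short probes (a probe set). The labels do not say whether the 3 samples of a genotype came from separate sowings or plants, so p-values measure the spread between these samples, which may be technical.

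The deposited values are signal intensities on a linear scale, 1 value per probe set and array. The submitters' processing notes name MAS5, an algorithm that computes the signal of a probe set from its perfect-match and mismatch probes, and its version and settings are not given in the sources used here. Each array had a mean of 100.01 after the lowest and highest 2% of its values were left out, so the arrays had already been scaled to a common trimmed mean. Array medians lay between 34.6 and 40.8. The number of arrays limits the precision.

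The table held 22746 probe sets and 64 control probe sets, which were left out of the tests. Gene names came from the platform annotation supplied with the values, updated through the gene identifiers of the TAIR10.1 assembly, which was used for names and for gene order. The annotation listed 14016 probe sets, 13513 of them with 1 gene and 503 with several, and 8730 had no entry and stay unnamed here. Of those with 1 gene, 13436 matched a locus (13286 loci) and 77 did not. No gene was named from a probe set with several genes, and a locus with several probe sets was represented by the one with the highest mean. SNI1 itself was paired with no probe set by this annotation and was not analysed here.

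Values were transformed as log2(value + 2.8668), the added constant being the 10th percentile of all values, so fold changes of low signals are understated. Probe sets with a mean over all arrays under 24.5, the 40th percentile of those means, were left out, and 13648 were tested. Genotypes were compared with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and fold changes are sni1 minus wild type. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Before the data were examined, 18 gene lists with 305 genes were fixed. Of these genes 42 had a named probe set and 32 were tested, and 5 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry (whether genes of a list move one way on balance) as alternatives.

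Both genotypes carry replicate numbers 1 to 3 in the sample titles. Whether these numbers pair the samples was checked from the deviations of each array from its genotype mean across probe sets. Same-numbered arrays deviated together (correlations of 0.66, 0.58 and 0.71 across probe sets, which are not independent replicates), while differently numbered arrays gave values from -0.53 to -0.05. Deviations within a genotype cancel by construction, so the negative values are no separate evidence. Judged by the same-numbered arrays, the numbers pair the samples. The pairing comes from the data and not from a statement in the labels. The fit with the replicate number as a block was fixed in advance as an alternative and is given beside a result where it changes the call.

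Genes were named by a rule fixed in advance: SNI1 and the gene that the labels name, the 12 largest positive and 12 largest negative fold changes among single-gene probe sets past the threshold whose genotypes did not overlap, and up to 4 members per list. Where fewer than 12 passed, genes with the smallest unadjusted p follow and are said not to pass. Families of genes with a shared symbol (at least 5 tested members) and the chloroplast-encoded genes were added after seeing the data. Alternatives covered the added constant, the filter, quantile normalization, median centring, cyclic loess, the variance trend, array weights, the replicate block and leaving out each array. Fits with a single array left out had no block. They keep the other array of that number without its pair, so differences between numbers can move them. Leaving out both arrays of a replicate number, the block with quantile normalization and, for the gene families, the block with median centring or cyclic loess were added after seeing the data.

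The procedure was tested on data simulated for this comparison with the observed means, replicate differences and residual spread of the 13648 probe sets, 200 of them changed. Of 100 probe sets changed by 1 on the log2 scale 5% were recovered, and of 100 changed by 2 74% were recovered, with 0 false calls. With the replicate block these shares were 40% and 84%, with 1 false call. Of 200 random lists of 9 unchanged genes, 1 gave an unadjusted camera p under 0.05. The residual spread was simulated independently for each probe set. These lists therefore cannot show how camera does where the genes of a list vary together.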

Results

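Transcript levels were measured in whole plants of wild-type Arabidopsis (Col-0) and of sni1, a mutant that the labels describe as induced by radiation, with 3 ATH1 arrays per genotype. SNI1 is known as a negative regulator of systemic acquired resistance, the defence state that follows local infection and depends on salicylic acid. The title of the series names the comparison of the transcript profiles of the 2 genotypes as its subject. All values are MAS5 signal intensities scaled to a common trimmed mean. The ratio of 3' to 5' signal of an actin pair of control probe sets, a measure of RNA integrity, was 3.85 ± 1.13 in wild type and 5.26 ± 2.18 in sni1 (SD, n = 3 each, two-sided exact permutation p = 0.4, where 0.1 is the smallest possible). The GAPDH ratio went the other way, at 1.498 ± 0.333 in wild type and 1.395 ± 0.195 in sni1 (exact permutation p = 0.6). Another actin pair had mean 3' and 5' signals of 1705.5 and 1067.9 in wild type and 1612.5 and 1058.5 in sni1. A difference in RNA integrity between the genotypes was not shown.

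The labels place the mutation in AT4G18460, the neighbour of SNI1 (AT4G18470) in the order of the TAIR10.1 assembly. The AT4G18460 signal was 39.4 ± 2.01 in wild type and 35.02 ± 8.35 in sni1 (SD, n = 3 each), a log2 fold change of -0.18 ± 0.21 (SE; limma adjusted p = 0.906). The AT4G18460 fold change ran from -0.35 to -0.049 with 1 array left out. The next gene, AT4G18465, stood at -0.16 (limma adjusted p = 0.933). SNI1 was not analysed here. Among 136 tested genes within 1 Mb of SNI1, 0 passed the threshold, against 26 of 7143 elsewhere (Fisher's exact test, two-sided p = 1). With the replicate number as a block these counts were 12 of 136 (8.82%) and 616 of 7143 (8.62%; Fisher's exact p = 0.878).

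Most probe sets past the threshold had higher signal in sni1. CHI (AT2G43570), annotated as a putative chitinase, an enzyme class that degrades the chitin of fungal walls, rose from 28.2 ± 0.853 in wild type to 321 ± 92.5 in sni1 (SD, n = 3 each; log2 fold change 3.35 ± 0.21 SE, limma adjusted p = 0.00184). AT1G57630 rose from 3.49 ± 0.456 to 47.7 ± 23.4 (log2 fold change 2.88 ± 0.42, adjusted p = 0.0333), and AT3G13950 from 4.86 ± 2.48 to 49.5 ± 10.1 (2.80 ± 0.36, adjusted p = 0.0214). The wild-type mean of AT1G57630 lay under the highest 10th percentile of the arrays (4.31), so the size of its rise is uncertain. CYP71B23, a cytochrome P450, rose from 39.0 ± 16.1 to 186 ± 39.7 (2.23 ± 0.31, adjusted p = 0.0283). The only named gene that fell past the threshold was WSD1, a wax ester synthase, from 75.3 ± 3.19 to 23.0 ± 8.33 (-1.64 ± 0.24, adjusted p = 0.0353). With 1 array left out, AT1G57630 was above the filter in 4 of the 6 fits and passed in 1 of these, not without wild-type replicate 1 or 2 or sni1 replicate 1 (adjusted p up to 0.0854). AT3G13950 was above it in 3 fits and passed in 2, not without wild-type replicate 1 (0.0530). Their log2 fold changes were 1.86 and 1.85 with the larger constant of the 25th percentile, against 3.01 for CHI, and 3.65 and 3.48 with no constant added, against 3.47 for CHI, so the order of these genes depended on the constant. CYP71B23 did not pass without wild-type replicate 3 or sni1 replicate 1 or 2 (up to 0.203). Of the fits with 1 array left out, WSD1 passed only in that without sni1 replicate 3 (adjusted p up to 0.195 in the others), and it did not pass without the filter (0.0703).

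**Figure D1:**
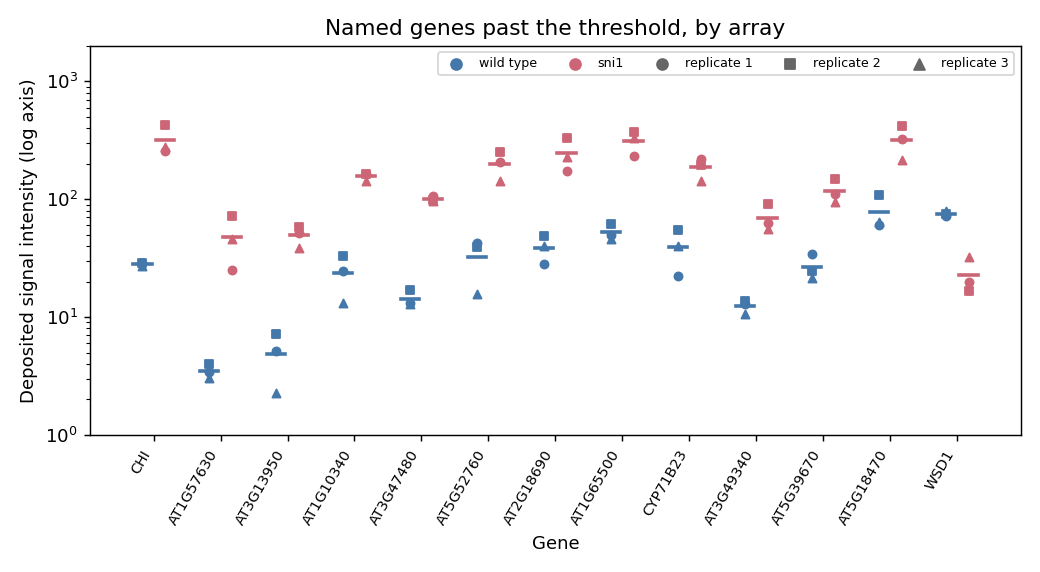
Deposited signal intensity (log axis) of the 13 named genes past the threshold, with 1 point per array, shapes for replicate numbers and bars for genotype means (n = 3). For CHI the 3 wild-type arrays lie between 27.2 and 28.7 and the 3 sni1 arrays between 256 and 427.

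The other genes of the 12 with the largest rise on the log2(value + 2.8668) scale were AT1G10340 (log2 fold change 2.67), AT3G47480 (2.60), AT5G52760 (2.59), AT2G18690 (2.55), AT1G65500 (2.49), AT3G49340 (2.22), AT5G39670 (2.03) and AT5G18470 (2.00), with limma adjusted p from 0.00225 to 0.0360. CHI and AT3G47480 passed with each of the 6 arrays left out (adjusted p up to 0.0142 and 0.0449). Without sni1 replicate 1 or sni1 replicate 2, AT1G10340 (adjusted p up to 0.0829), AT2G18690 (0.0757) and AT3G49340 (0.0987) did not pass, and AT1G65500 did not pass without sni1 replicate 2 (0.0515). AT5G39670 did not pass without wild-type replicate 2 or sni1 replicate 1 or 2 (up to 0.0831). AT5G52760 did not pass without wild-type replicate 1 or 2 or sni1 replicate 1 or 2, nor AT5G18470 without wild-type replicate 1 or 3 or sni1 replicate 1 or 2 (up to 0.206 for both), and neither passed without the filter (0.0505 and 0.0519). These fits had no replicate block. With the block and all 6 arrays, the 12 genes and WSD1 passed (limma adjusted p from 1.94e-06 for CHI to 0.000702 for AT1G57630). The largest rise on this scale was that of a probe set with no gene in the annotation used here, from 75.6 ± 11.3 to 1304 ± 254 (SD, n = 3 each; log2 fold change 4.05 ± 0.20 SE, limma adjusted p = 0.000572), which passed with each array left out (adjusted p up to 0.00672).

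In all, 75 of 13648 probe sets passed (71 higher and 4 lower in sni1), each by at least 2-fold, and 26 of them had 1 locus, 2 several genes and 47 no gene name. In these 75 the arrays of the genotypes did not overlap, which was so for 14.4% of all tested probe sets. Chance would give 10% for arrays without pairing. The replicate numbers pair these arrays, so the 10% is not a fitting reference. All 3 same-numbered pairs went one way in 46.6% of the tested probe sets and in each of the 75. A chance level for that share was not computed. At an unadjusted p under 0.05 there were 1159 (744 higher and 415 lower). With the replicate block, 1369 probe sets passed (839 higher and 530 lower), 313 of them by at least 2-fold, and all 75 were among them. The share of higher calls was 94.7% without the block and 61.3% with it. Leaving out sni1 replicate 1 or sni1 replicate 2 reduced the 75 calls to 5 each, leaving out wild-type replicate 1 to 37 and wild-type replicate 2 to 42. CHI passed in each of these.

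Further genes with lower signal in sni1 did not pass without the replicate block and passed with it. They were AT5G50740 (log2 fold change -0.99, adjusted p = 0.0823 without and 0.00633 with the block), AT2G18890 (-0.91, 0.0875 and 0.00172), AT1G68780 (-0.85, 0.0867 and 0.00548) and CYTC6A, a cytochrome c6A (-0.76, 0.103 and 0.00750). The same held for AT5G02890 (-1.02), AT3G21950 (-1.02), AT2G39850 (-0.93), KICP-02 (-0.87), AT5G06630 (-0.84), AT4G18970 (-0.82) and AT3G17120 (-0.82), with adjusted p from 0.123 to 0.171 without the block and from 0.000660 to 0.0149 with it. The AT5G06630 probe set is of a type whose probes can match more than 1 transcript, so its fall may not be of that gene alone. With array weights and no block, AT2G18890 (adjusted p = 0.0335), AT1G68780 (0.0456) and AT2G39850 (0.0456) also passed. Over the alternative settings fixed in advance the adjusted p of these genes with lower signal ran from 0.000660 to 0.502.

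**Figure D2:**
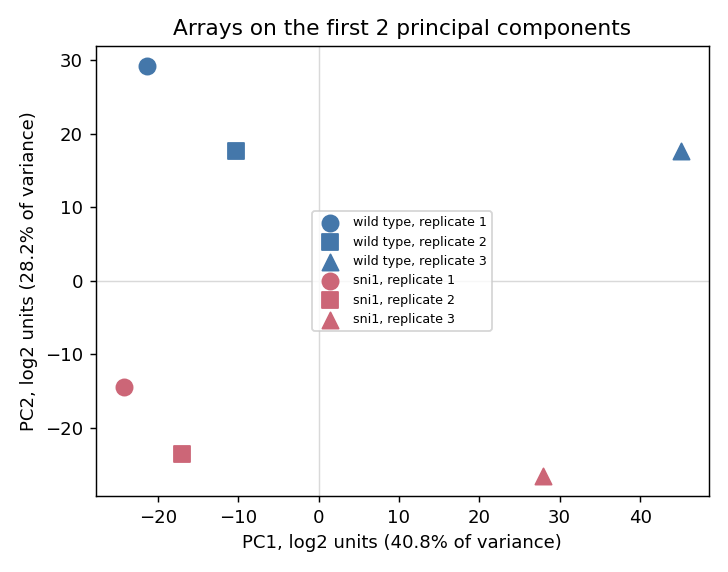
First and second principal components of the log2 values of 13648 probe sets, with 1 point per array, colours for genotypes and shapes for replicate numbers. The first component (40.8% of the variance) sets both arrays of replicate 3 apart at 45.0 and 27.9, and the second (28.2%) separates the genotypes.

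Of the salicylic acid and systemic acquired resistance list, 4 of 39 genes were tested. WRKY53, a transcription factor of senescence and defence, had a signal of 49.8 ± 18.7 in wild type and 147 ± 56.3 in sni1 (SD, n = 3 each; log2 fold change 1.49 ± 0.37; limma adjusted p = 0.226), and rose with the replicate block (adjusted p = 0.000110). SAG101, a lipase-like defence protein (1.097 ± 0.27), and GRX480, a glutaredoxin (0.87 ± 0.42), passed only with the block (adjusted p = 0.00496 and 0.0143), and AT5G03350 did not pass (0.34, adjusted p = 0.967 without and 0.380 with it). GRX480 stood at 0.50 without wild-type replicate 3 and at 0.55 without sni1 replicate 1. The count of higher members was 0 over all genes tested and 2 adjusted over the list alone, and 3 and 3 with the block. The median log2 fold change was 0.98 (camera adjusted p = 0.00379). That call was lost with an estimated correlation (adjusted p = 0.503 with an estimated correlation; fry adjusted p = 0.390), and without wild-type replicate 3 (median 0.65, camera adjusted p = 0.0747). Over the alternative settings fixed in advance adjusted p ran from 0.000110 to 0.638 for WRKY53, from 0.00496 to 0.580 for SAG101 and from 0.0143 to 0.926 for GRX480.

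Both tested genes of the ethylene and jasmonate defence list, of 7 fixed, had higher signal in sni1. The plant defensin genes PDF1.2b (63.7 ± 78.0 to 431 ± 229, log2 fold change 3.25 ± 0.78) and PDF1.2 (41.3 ± 18.0 to 175 ± 80.9, 1.99 ± 0.37; SD, n = 3 each) rose with the replicate block (limma adjusted p = 0.00138 and 0.00289) and did not pass without it (0.199 and 0.0854). The count was 0 over all genes and 2 adjusted over the list alone, and 2 and 2 with the block. Without wild-type replicate 3, in which PDF1.2b stood at 154 against 15.0 and 22.4 in the other wild-type arrays, both passed without the block (adjusted p = 0.0132 and 0.0433), as they did with array weights (0.0347 and 0.0179). The PDF1.2b probe set is of a type whose probes can match more than 1 transcript, so the 2 rises may not be separate. With 2 tested members the list had no camera test. Over the alternative settings fixed in advance adjusted p ran from 0.00138 to 0.595 for PDF1.2b and from 0.00289 to 0.274 for PDF1.2.

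**Figure D3:**
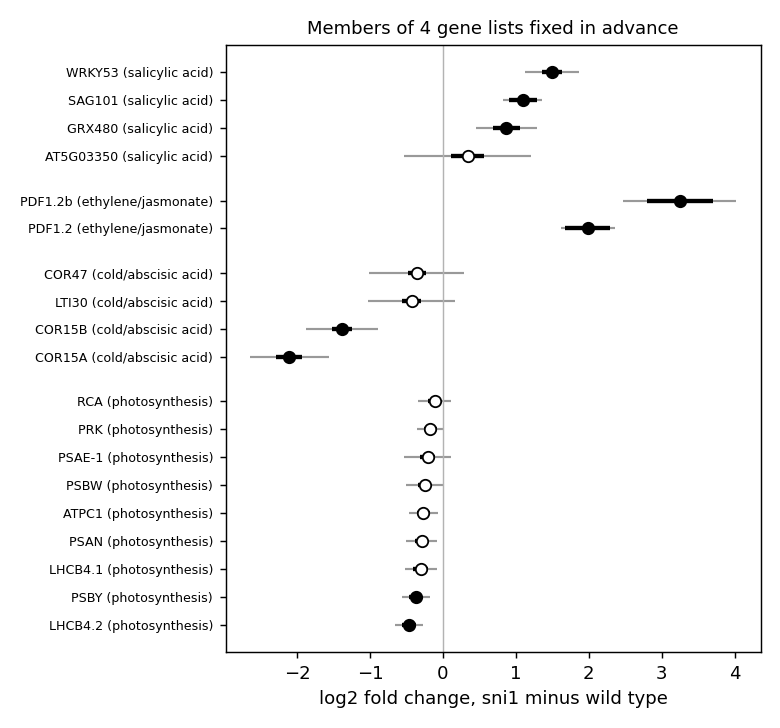
Log2 fold change (sni1 minus wild type) of each tested member of 4 lists, with standard errors of the fit without the replicate block (grey) and with it (black). Filled points, such as WRKY53 at 1.49 and COR15A at -2.10, passed the adjusted threshold with the block, and open points did not.

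Of the cold and abscisic acid list, 4 of 14 genes were tested and all had lower mean signal in sni1. COR15A (1518 ± 800 to 358 ± 199, log2 fold change -2.10 ± 0.54) and COR15B (1708 ± 766 to 668 ± 355, -1.38 ± 0.50; SD, n = 3 each), which encode chloroplast proteins that accumulate in the cold, fell with the replicate block (limma adjusted p = 5.82e-05 and 0.000177) and did not pass without it (0.246 and 0.456). LTI30 (-0.43) and COR47 (-0.36) did not pass in either fit. Both were lower in sni1 in each same-numbered pair, in replicate 3 from 200 to 143 and from 2490 to 1466. Without wild-type replicate 3 they stood at 0.14 and 0.31. That fit had no block and kept sni1 replicate 3 without its pair, so its change of sign does not show a rise. COR47 also differed between replicate numbers and averaged 1978 over both genotypes in replicate 3, 790 in replicate 1 and 424 in replicate 2. The count of lower members was 0 over all genes and 2 adjusted over the list alone, and 2 and 4 with the block. The median was -0.91 (camera adjusted p = 0.00920), and the call was lost with an estimated correlation (adjusted p = 0.503 with an estimated correlation), without wild-type replicate 3 (median -0.48, camera adjusted p = 0.325) and without sni1 replicate 2 (-0.47, 0.132). Without wild-type replicate 2 the median was -1.37. Over the alternative settings fixed in advance adjusted p ran from 5.82e-05 to 0.585 for COR15A and from 0.000177 to 0.898 for COR15B.

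Of the photosynthesis list, 9 of 42 genes were tested, with a median log2 fold change of -0.27 (camera adjusted p = 0.00647). The call was lost with an estimated correlation (adjusted p = 0.539 with an estimated correlation). LHCB4.2, a light-harvesting antenna protein (4400 ± 755 to 3156 ± 265, -0.47 ± 0.19; SD, n = 3 each), and PSBY, a photosystem II protein (4583 ± 593 to 3539 ± 451, -0.37 ± 0.19), fell with the replicate block (limma adjusted p = 0.0125 and 0.0202) and did not pass without it (0.549 and 0.695). Their log2 fold changes were -0.27 and -0.21 after quantile normalization and -0.28 and -0.18 after cyclic loess. With the block and quantile normalization LHCB4.2 passed (adjusted p = 0.0340) and PSBY did not (0.101). LHCB4.1 (-0.30) and PSAN (-0.29) did not pass in either fit. With 1 array left out they ran from -0.45 to -0.12 and from -0.41 to -0.11, and after quantile normalization they stood at -0.061 and -0.086. The count of lower members was 0 over all genes and 0 adjusted over the list alone, and 2 and 6 with the block. The list's call was lost without wild-type replicate 3 (median -0.11, camera adjusted p = 0.325) and without sni1 replicate 2 (-0.15, 0.132), while without wild-type replicate 2 the median was -0.43. It was also lost after quantile normalization (median -0.07, camera adjusted p = 0.428) and cyclic loess (-0.07, 0.292), and without the filter (0.0514). Over the alternative settings fixed in advance adjusted p ran from 0.0125 to 0.898 for LHCB4.2 and from 0.0202 to 0.966 for PSBY.

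The remaining lists held few tested genes. For the list of the secretory pathway and endoplasmic reticulum chaperones, 3 of 16 genes were tested, with a median of 0.31 (camera adjusted p = 0.564). This median ran from 0.12 without sni1 replicate 1 to 0.57 without sni1 replicate 3. ATERDJ3B, a co-chaperone (0.39, and from 0.22 to 0.64 with 1 array left out), AT5G07340 (0.31) and AT2G34250 (-0.15) did not pass without or with the block, the count of higher members adjusted over the list alone being 0 without and 1 with the block. The 3 tested reference genes of 11, AT2G28390, PEX4 and AT4G34270, lay between -0.15 and 0.05 (list adjusted p = 0.573). Of the homologous recombination and SMC5/6 complex list, 2 of 22 were tested, AT2G28130 (0.21) and AT1G34770 (-0.15), neither past the threshold. The DNA damage response list had 0 tested members of 23, and its only member with a named probe set, MND1, lay under the filter (13.4 and 9.86). WRKY6, the single tested gene of the senescence list, stood at 0.85 (limma adjusted p = 0.398 without and 0.0550 with the block). It passed with the block after quantile normalization (0.0404), median centring (0.0469) and cyclic loess (0.0356). BCAT4 (0.16), GI (-0.03), AUR1 (-0.12) and PRL (-0.44), the single tested genes of the aliphatic glucosinolate, circadian clock, mitotic cell cycle and DNA replication lists, did not pass. With 1 array left out, PRL ran from -0.77 to -0.13 and AUR1 from -0.26 to -0.011. With 1 tested gene in a list, the limma p adjusted over the list alone is the unadjusted p, 0.0157 for WRKY6 and 0.228 for PRL (0.0222 with the block). Jasmonate, camalexin, heat shock, flower and root marker lists had 0 tested members.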

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

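The tests in this part on the control-section probe set were chosen after its values were seen, while those on the differences between replicate numbers were written before their results were seen.

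A probe set in the array's control section, which the comparisons leave out, stood at 21.6 ± 2.45 in wild type and 331 ± 105 in sni1 (SD, n = 3 each; log2 fold change 3.72 ± 0.25, limma adjusted p = 0.00303 over 22810 probe sets). What it detects is not given in the sources used here. Scaling or hybridisation of the arrays should move the other controls, but the 35 others above the filter value had a median of -0.080 and ranged from -0.42 to 0.43. A single deviant array is argued against by the lowest sni1 array being 9.70 times the highest wild-type array. A difference in the plants, such as sequence carried by the sni1 line alone, may remain as a candidate explanation and was not tested.

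Below the filter lay 9098 probe sets. In fits over all probe sets, 3 of them passed as higher and 0 as lower in sni1, while 52 passed as higher and 10 as lower with the replicate block. Singled out after their values were seen, AT1G26380 rose from 0.988 ± 0.414 to 24.7 ± 10.1 (limma adjusted p = 0.0320) and, with the block, RAD5, a DNA repair gene, fell from 13.1 ± 4.42 to 2.31 ± 0.297 (adjusted p = 0.164 without and 0.0433 with the block). The lower mean of each gene, in wild type for AT1G26380 and in sni1 for RAD5, did not exceed the highest 10th percentile of the arrays, which ran from 1.81 to 4.31.

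The replicate numbers differed in 4252 of the 13648 probe sets (31.2%), 752 of them also called between genotypes with the block. Replicate 3 differed most: its arrays had 10th percentiles of 1.81 and 1.89 against 3.34 to 4.31, and GAPDH control ratios of 3' to 5' signal of 1.12 and 1.17 against 1.503 to 1.75. The actin control ratios did not set replicate 3 apart (4.22 and 3.29 against 2.58 to 7.61). Unequal scaling is argued against, since 4186 probe sets differed after quantile normalization, 3834 of them among the 4252. Noise at low signal is argued against, since 54.0% of the brightest 3412 probe sets differed. A separate growth, harvest, labelling or hybridisation of each number may be the source; the labels record none of these, and no biological explanation was tested.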

How the results depend on the processing

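Leaving out both arrays of a replicate number, and the block with quantile normalization, were chosen after seeing the data. The replicate block gave 1369 changed probe sets in place of 75 (839 higher, 530 lower, 313 at least 2-fold) and 12 calls near SNI1 in place of 0, and it changed no other call than those given beside a result. The block with quantile normalization gave 1446 (838 higher, 608 lower, 317 at least 2-fold). All 75 were kept in both. The block without both arrays of replicate 1, 2 or 3 gave 1143, 786 and 1049 changed (734, 495 and 668 higher, 409, 291 and 381 lower, 362, 296 and 327 at least 2-fold). Without the block, leaving out both arrays of replicate 1 gave 0 of each, of replicate 2 gave 3 changed, 3 higher, 0 lower and 3 at least 2-fold, and of replicate 3 gave 59 changed, 58 higher, 1 lower and 59 at least 2-fold, and the cause was not tested. Array weights gave 137 changed, 124 higher, 13 lower and 125 at least 2-fold, and the cause was not tested. The filter at the 60th percentile, with fewer probe sets tested, gave 46 changed, 43 higher and 46 at least 2-fold, and no filter gave 1 lower. Leaving out 1 array gave 5 to 72 changed, 5 to 69 higher, 0 to 3 lower and 5 to 72 at least 2-fold.

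The salicylic acid list kept its direction, with medians of 0.65 to 1.26 when 1 array was left out. It lost its call with an estimated correlation and with fry (both at a median of 0.98) and without wild-type replicate 3, and the cause was not tested. Adjusted p ran from 0.000225 to 0.503 over its alternatives. Fry likewise did not call the cold and photosynthesis lists (adjusted p = 0.390), and the block with quantile normalization did not call the photosynthesis list (0.277). At the 60th percentile filter the salicylic acid list had too few members. The homologous recombination list was tested only without the filter (5 members, median -0.09, adjusted p = 0.950), as was the mitotic list (3 members, -0.12, 0.950). The DNA damage list and SNI1 could not be tested.

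The 13 named genes past the threshold kept their direction in all 287 values under 23 settings, and passed in 226. They were chosen as genes whose genotypes did not overlap, so leaving out arrays could not change their direction. For the other 39 named genes, 22 of 880 values changed sign, none past the threshold, and the cause was not tested. With the block, leaving out both arrays of a number ended the calls of PSBY (replicate 1 or 2), AT1G68780, CYTC6A and AT3G17120 (replicate 2) and KICP-02 (replicate 1), with adjusted p from 0.0532 to 0.127. It gave calls to AT5G03350 and COR47 (replicate 1) and to ATERDJ3B, AT5G07340 and PRL (replicate 3), with adjusted p from 0.0161 to 0.0455, and the block with quantile normalization gave calls to LTI30 (0.0494) and WRKY6 (0.0404). With 1 array left out, GI ran from -0.29 to 0.17, AT5G03350 from -0.65 to 1.16, BCAT4 from -0.15 to 0.42, LTI30 from -0.98 to 0.14, COR47 from -0.92 to 0.31, and PEX4 and the reference list from -0.15 to 0.018. GI reached 0.018 with array weights. With and without the block, leaving out both arrays of replicate 3 gave GI 0.042, AT5G03350 -0.10 and AT4G34270 -0.015, and leaving out both of replicate 2 gave AT1G34770 0.014 and AUR1 0.0067. Signals near the pseudocount limit what low probe sets can show.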

Other observations

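The gene families, the genes named from them and the test of neighbouring genes were chosen after the data were seen. A first version of the neighbour test, on shared probe design, had been written before but presupposed an excess of neighbouring calls that was absent.

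Of 4 tested endoglucanase genes 3 fell with the replicate block, and of 5 tested expansin genes 2 did. The endoglucanase genes GH9C2 (log2 fold change -0.98), GH9B8 (-0.80) and GH9B7 (-0.58) and the expansin genes EXPA16 (-0.93) and EXPA8 (-0.93) fell (limma adjusted p from 0.000308 to 0.0359 with the block), and none passed without the block. GH9A3 (-0.098), EXPA15 (-0.43), EXPA4 (0.073) and EXPA9 (0.25) did not pass with it (adjusted p from 0.159 to 0.810), and camera did not call the EXPA family (adjusted p = 0.123). Of 5 tested beta-tubulin genes, TUB1 (-0.77), TUB7 (-0.56) and TUB6 (-0.43) fell with the block and TUB5 and TUB9 did not pass. RALFL34, a peptide hormone gene (-0.81), was the only 1 of 5 tested RALFL genes that fell with the block (adjusted p = 0.000444). These calls with the block held with quantile normalization, median centring and cyclic loess.

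Among 34 families, camera called TUB (adjusted p = 0.0349), GH (0.0381) and RALFL (0.0496) lower and PDF (0.0349) and WRKY (0.0381) higher. All 5 calls were lost with an estimated correlation (adjusted p from 0.443 to 0.563 with an estimated correlation). With the replicate block, TUB kept its call (0.0180, but adjusted p = 0.634 with the block and an estimated correlation) and PDF (0.0624), GH (0.0624), WRKY (0.0547) and RALFL (0.0547) lost theirs, and RALFL also lost its call with quantile normalization (0.0620), median centring (0.0533) and cyclic loess (0.0580). None of these 5 families changed direction among the 4 scalings. The PDF symbols mix defensins with the peptide deformylases PDF1A (-0.06) and PDF1B (-0.29), and GH mixes the endoglucanases with GH3.3 (0.72), an auxin-conjugating enzyme.

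Further genes rose with the block, under the deposited scaling and the 3 others: WRKY47 (1.103, limma adjusted p = 0.00283), PDF1.4 (1.63, 0.000886), and the glutamate receptor-like genes GLR2.7 (1.12, 0.00136) and GLR1.4 (0.98, 0.00279). None of these passed without the block (adjusted p from 0.0817 to 0.281). Of 5 tested members each, 2 WRKY, 3 PDF and 2 GLR genes rose with the block under the deposited scaling, and 3 WRKY genes, WRKY6 included, under each of the 3 others. The 3 PDF genes include PDF1.2b, whose probe set can match more than 1 transcript. GLR3.3 (0.26), GLR3.5 (-0.064) and GLR3.6 (-0.34) did not pass with it (adjusted p from 0.267 to 0.856), and camera did not call the GLR family (adjusted p = 0.110 without and 0.127 with the block).

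The chloroplast-encoded genes varied with the replicate number. Of 69 tested, 44 differed between numbers, and 42 of the 69 were higher in replicate 3, with a median over the 69 of 0.20 above the other numbers. The gene cemA, which had the smallest p of these genes for this difference, averaged 2708 in replicate 3 against 1001 and 827. Their median difference between genotypes was -0.13 (camera adjusted p = 0.110; 0.0180 with the replicate block, and adjusted p = 0.739 with the block and an estimated correlation). With quantile normalization it was -0.04 and with cyclic loess -0.03.

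Whether genes called with the block lie next to each other was tested as a hypothesis. Of 2135 neighbouring tested pairs in the gene order of TAIR10.1, 10 were called the same way, among them AT5G52750 with AT5G52760 and COR15B with COR15A, against 8.20 on average in 10000 permutations (one-sided permutation p = 0.305). Among probe sets of unique design there were also 10 pairs against 8.23 (one-sided permutation p = 0.309). An excess was not shown, and the number is too small to exclude a modest one.

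The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 75 called probe sets and the highest other 0, and 1 split of the 10 gave as many. Of the 4 splits that part all 3 pairs, with the block the real one gave 1369 and the highest other 0, so 1 gave as many. The other 6 splits keep 2 pairs together and were not fitted with the block. For the salicylic acid list, the real split gave an absolute median of 0.98 and the highest other 1.04, from wild-type replicate 1 with sni1 replicates 1 and 2 against the rest, which parts 1 pair, and 2 splits gave a value as large.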
